A study of Arabidopsis thaliana with 12 samples.

How the data were processed

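Messenger RNA from whole Arabidopsis thaliana seedlings was sequenced in 12 libraries, 3 for each of 4 genotypes named in the labels: Col-0 (the wild type), a cfh1 mutant, a CFH1 decoy line and a PIF3 over-expression line. The titles of the PIF3 libraries call the line a pif3 mutant, whereas their genotype and description fields say over-expression, and the group was taken from those fields. Per the labels, seedlings were grown for 7 days in cycles of 12 h light and 12 h dark, then moved to constant red light. They were collected on day 12 at zeitgeber time 1, which counts hours from a dawn that constant light no longer marks. With 1 collection time, a changed level of a cycling gene cannot be told apart from a shift in the timing of its cycle, in any line. RNA was extracted with TRIzol, and 5 to 20 ng went into an mRNA library kit. Nothing in the labels says that the 3 libraries of a genotype came from separate cultures or plates, so p-values measure the spread between these samples.

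The authors deposited a table of estimated counts, the fractional read counts that a quantification tool assigns to genes, for 27588 genes named by AGI locus code. Of its values, 41.57% were not whole numbers at a tolerance of 1e-09. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.1.0, StringTie 2.1.2 and the TAIR10 build, without a role for each, and the step that made the counts and its handling of strand are not given in the sources used here. Estimated counts share reads between near-identical genes by a model, so values of single members of the SAUR19 to SAUR24, LHCB1, LHCB2, RBCS, PP2-A and PDF1.2 groups and of AT14A can borrow from each other. Counts were rounded to whole numbers before the fits. Of the locus codes, 27378 matched the TAIR10.1 reference annotation, which supplied names and products alone, and 2915 genes had 0 counts in every library.

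Total counts ran from 21914394 to 34345088 per library. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by group (minimum count 10), which left 21235, and libraries were scaled with TMM (trimmed mean of M-values) factors. A quasi-likelihood model with 1 mean per genotype was fitted to all 12 libraries (8 residual degrees of freedom, common biological coefficient of variation 0.172). Each line was compared with Col-0 and each pair of lines with one another by 2-sided tests with Benjamini-Hochberg adjustment over the genes tested, at a threshold of 0.05. Values are CPM, edgeR's counts scaled to a common library size with the TMM factors, as mean ± SD over 3 libraries (n = 3), and log2 fold changes come from the edgeR fit with their SE. A fold against a group at 0 was set against a floor of 3 counts over the group, at the smaller of the values from the pooled counts and from the mean CPM of the other group where both were computed, and groups with 1 to 3 counts have a ratio with a 95% interval. Intervals and floors cover counting error only.

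The comparisons, tests, gene lists and alternatives were fixed before the data were examined. The rule for named genes took, per line against Col-0, the 8 largest rises and 8 largest falls of nuclear genes with a symbol, an adjusted p under 0.05, a mean log2 CPM of at least 1 and all 3 libraries on 1 side of all Col-0 libraries. Pairs of lines took 5 and 5. Lists with at least 2 changed members added up to 3 members each, shared changes added 5 per direction, and PIF3, PHYB, CCA1, LHY, TOC1 and PIL1 were always named, and genes named outside this rule are said to have been chosen after their values were seen. The name CFH1 is not paired with a locus in the sources used here.

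The 18 gene lists held 313 members, drawn from general knowledge: dawn-phased and evening-phased clock genes, phytochrome and light signalling, B-box factors, shade and PIF-induced genes, auxin early response, gibberellin and brassinosteroid genes, cell wall loosening, light harvesting and Rubisco, chlorophyll synthesis, flavonoid and anthocyanin, cold, drought and abscisic acid, heat shock, salicylic acid and defence, jasmonate, flowering time, cell division and root markers. None was chosen on these samples. Each was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 18 lists of a comparison, and again with an estimated correlation and with fry, which asks whether the members move on balance 1 way. The counts "adjusted over the list alone" adjust the edgeR p-values over a list's members.

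The pipeline was tested on simulated data with 50 genes changed at each size in 1 arm of 3 libraries. The changed genes were drawn from those at a level of 1 CPM or more, so recovery below that level was not tested. It recovered 14% of 1.5-fold changes, 64% of 2-fold, 98% of 4-fold and 98% of 8-fold changes, with 5 false calls. Alternatives fixed beforehand were RLE size factors, library totals alone, DESeq2 1.42.0, no filter (24673 genes), a stricter filter (CPM of 1 in 3 libraries and a mean count of 50, 18721 genes), the libraries of the 2 groups alone, replicate number as a block, leaving out each library in turn, removal of 198 plastid, mitochondrial and rRNA genes, and an absolute log2 fold change of at least 1. A fit without the decoy libraries and a fit without genes at 3 counts or fewer in a whole group, and counts of shared genes at an unadjusted p under 0.05, were chosen after seeing the data. No library and none of the 12 columns was left out of the main comparisons. Of the genes with the largest differences, 1 is not reported here.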

Results

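Gene expression was measured in whole Arabidopsis thaliana seedlings of 4 genotypes under constant red light, with 3 libraries each. CFH1 is an F-box protein that the series title links to the circadian clock and red-light development, and PIF3 is a basic helix-loop-helix factor that binds phytochrome. A decoy is usually an over-produced F-box protein without its F-box, which binds targets without passing them on for ubiquitination. Total counts were 33583770, 32504508 and 28581600 for Col-0 replicates 1, 2 and 3, and 28664312, 27412570 and 30776728 for cfh1. They were 21914394, 34345088 and 33122683 for the decoy, and 31631824, 31333924 and 32309836 for PIF3 over-expression. Between 21832 (decoy replicate 1) and 22943 genes (PIF3 over-expression replicate 1) were detected. Plastid-encoded transcripts took 0.737% to 1.62% of counts. The 10 most abundant genes took 8.99%, 7.65% and 7.74% in the decoy libraries, 4.08%, 5.02% and 5.04% with PIF3 over-expression and 5.88% to 6.26% elsewhere. Rank correlations between libraries of a genotype were lowest in the decoy (0.975 to 0.981) and reached 0.996 in Col-0.

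**Figure D1:**
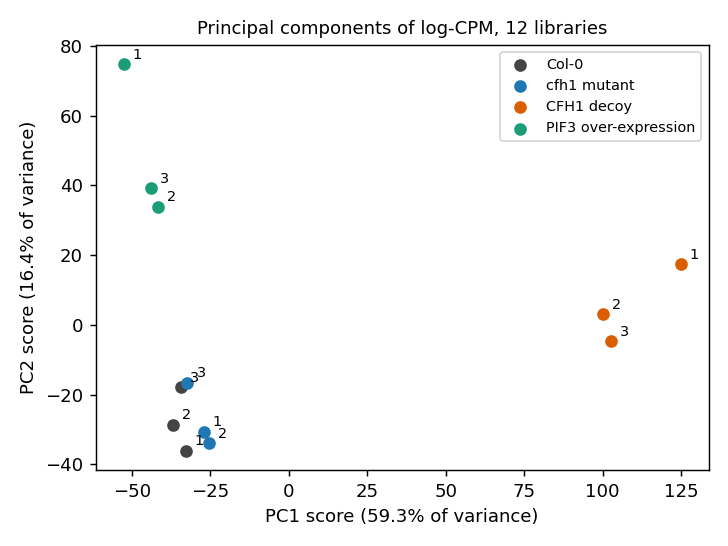
Principal components of log2 CPM, with 1 point per library and colours for the genotypes. Component 1 (59.3% of the variance) holds the decoy libraries between 100 and 124.9 and all others between -52.66 and -25.34, and component 2 (16.4%) holds PIF3 over-expression between 33.93 and 74.81.

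PIF3 transcripts were 12.3-fold more abundant in the libraries labelled PIF3 over-expression than in Col-0 (353.9 ± 8.05 against 28.8 ± 7.32 CPM, n = 3, log2 fold change 3.62, SE 0.228, edgeR adjusted p 5.34e-06). Each of the 3 libraries had 11746 to 12914 PIF3 counts, against 558 to 1121 in the other 9. PIF3 showed log2 fold changes of -0.11 in cfh1 and 0.27 in the decoy, and neither passed the test. The phytochrome gene PHYB did not pass in any line, at 0.08 in cfh1, 0.17 in the decoy and 0.13 with PIF3 over-expression. The evening clock gene TOC1 did not pass either, at 0.20, 0.13 and 0.12.

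**Figure D2:**
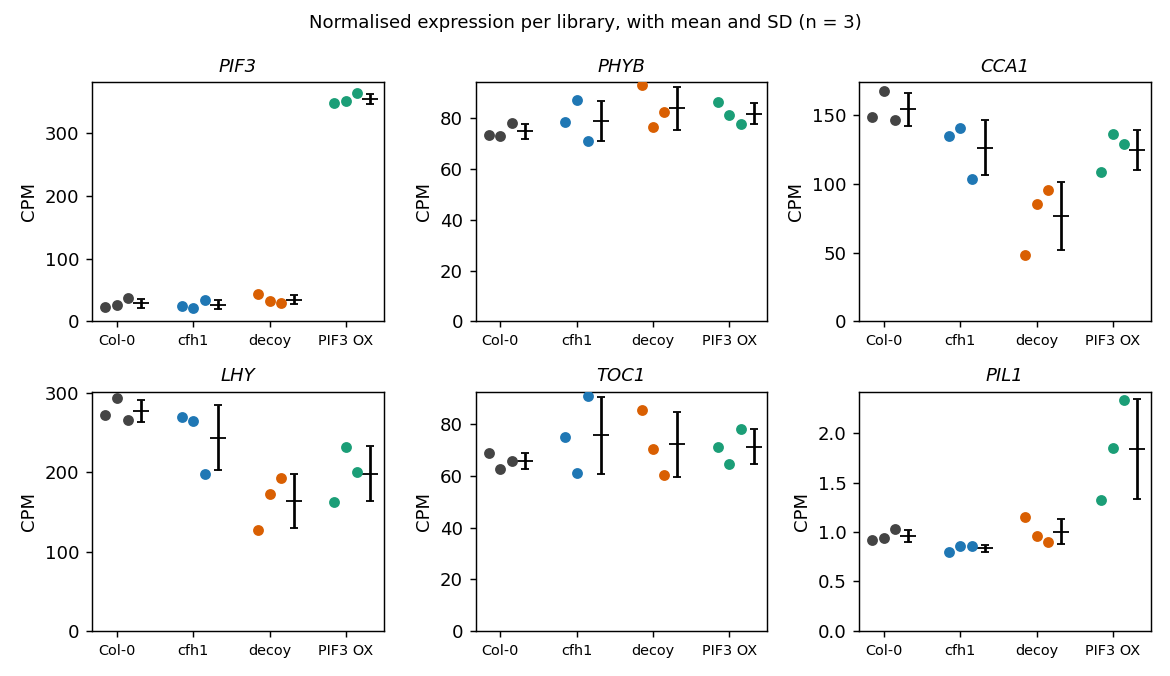
CPM of PIF3, PHYB, CCA1, LHY, TOC1 and PIL1 in each library (points), with the mean and SD of each genotype (n = 3). PIF3 stands at 353.9 CPM in PIF3 over-expression and 28.8 in Col-0, and CCA1 at 76.6 CPM in the decoy against 154.3 in Col-0.

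A mutation of CFH1 was asked about through the cfh1 mutant, and few transcripts differed from Col-0. Whether the mutant lacks CFH1 could not be tested, since the name is not paired with a locus. The comparison cannot tell an effect of CFH1 from another difference of the line. UBP6, a ubiquitin-specific protease gene, fell to 0.0978 ± 0.0578 CPM from 49.4 ± 1.81 (log2 fold change -8.87, SE 0.238, adjusted p 3.37e-10). MRD1 fell to 0.217 ± 0.0404 from 43.5 ± 3.05 CPM (-7.64), and HEI10, which acts in meiotic crossover formation, fell to 1.1 ± 0.278 from 8.67 ± 0.152 CPM (-2.98). OBE1, a PHD-finger gene of meristem maintenance, fell to 32.5 ± 2.27 from 65.4 ± 5.99 CPM, PEPKR1, a protein kinase gene, to 23.5 ± 2.81 from 46.4 ± 3.595, and ATI1, of selective autophagy, to 22.2 ± 2.64 from 44.7 ± 4.35. In total, 12 genes were lower and 3 higher of 21235 tested, and 31 and 7 by DESeq2. At an unadjusted p under 0.05 by edgeR, 517 were lower and 447 higher, together a share under 0.05, which unchanged genes alone could give. By DESeq2, 660 were lower and 461 higher of 24645, also a share under 0.05. In a fit of the 2 groups alone, however, 1073 were lower and 933 higher of 20719. Without the decoy libraries they were 964 and 931 of 21023. Both are shares above 0.05, so whether unchanged genes alone could give such counts depends on the fit. With library totals alone, 6 genes were higher at the adjusted threshold. Leaving out cfh1 replicate 2 left 7 lower genes, and leaving out single libraries left 2 or 3 higher. ATI1 did not pass without Col-0 replicate 3 (-0.94) or cfh1 replicate 2 (-0.93).

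Of the genes lower in cfh1, 6 carry no symbol and are named here after their values were seen. AT1G51720, which lies next to UBP6, stood at 0.252 ± 0.109 CPM against 33.0 ± 1.24 (-6.97). AT5G11330 stood at -1.32, AT4G14270 at -1.53, AT2G27830 at -1.31, the F-box gene AT2G32560 at -1.31 and AT1G20270 at -1.06. The 3 higher genes were AT1G75945 (5.26), AT5G37940 (3.15) and AT1G64795, which had 259 counts in cfh1 and 2 in Col-0, a ratio of 143 (95% interval 39.3 to 1191). AT2G32560 did not pass without cfh1 replicate 1 (-1.26) or 2 (-1.31), AT2G27830 without cfh1 replicate 1 (-1.31) or 2 (-1.19), and AT4G14270 without Col-0 replicate 3 (-1.42) or cfh1 replicate 1 (-1.46) or 2 (-1.43). AT1G20270 did not pass without Col-0 replicate 1 (-1.07), 2 (-1.02) or 3 (-1.09) or cfh1 replicate 1 (-1.02) or 2 (-0.94). AT5G37940 did not pass without Col-0 replicate 1 (3.58), 2 (3.2) or 3 (2.79) or cfh1 replicate 1 (3.15) or 3 (2.85). Neither AT1G20270 nor AT5G37940 passed in a fit of the 2 groups alone (-1.07 and 3.14) or with replicate number as a block (-1.06 and 3.16).

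**Figure D3:**
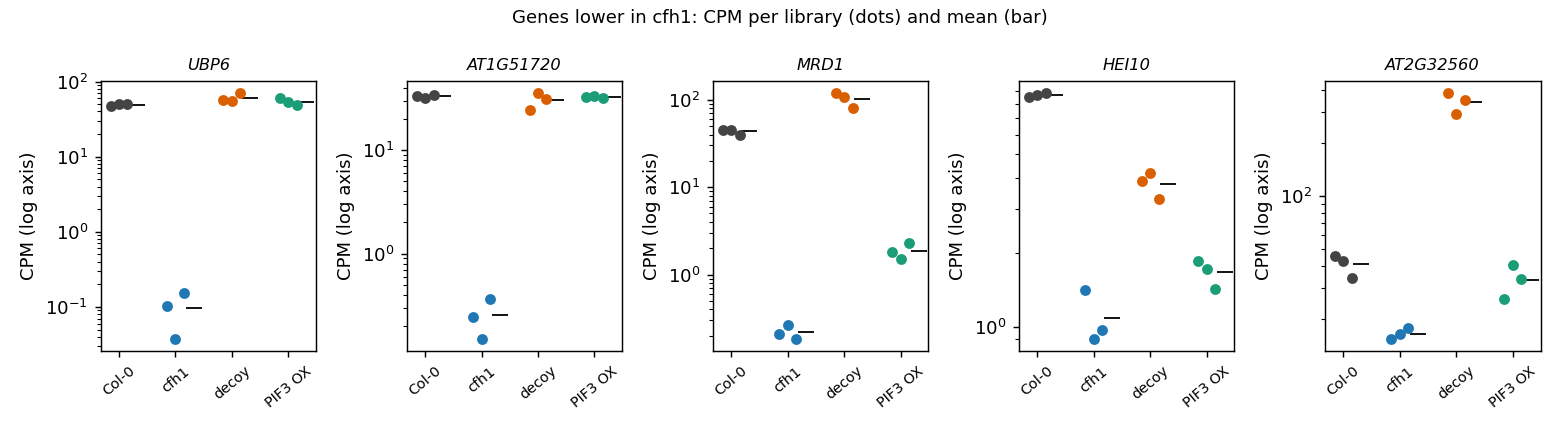
CPM on a log axis of UBP6, AT1G51720, MRD1, HEI10 and AT2G32560 in each library (points), with a bar at each genotype mean. UBP6 averages 0.0978 CPM in cfh1 and 49.4 in Col-0, and MRD1 is low in cfh1 (0.217) and in PIF3 over-expression (1.88).

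The clock and light genes named beforehand showed no change past the test in cfh1. CCA1 and LHY, the morning clock factors, stood at log2 fold changes of -0.29 (SE 0.207) and -0.18 (SE 0.178), and PIL1, a phytochrome-responsive factor, at -0.20 (SE 0.281). No member of the 18 gene lists passed edgeR's test over all genes. At an unadjusted p under 0.05 in the fit of all 12 libraries, 7 were higher and 2 lower of 300. Together this is a share under 0.05, which unchanged genes alone could give, but such members were not counted in other fits. The floral repressor FLC was lower by DESeq2 and when adjusted over the list alone, the only member in either case. By camera, auxin early response genes stood higher (adjusted p 0.00109), and flavonoid and anthocyanin (0.000425) and cell division genes (0.0439) lower. These calls were lost with an estimated correlation (adjusted p = 0.753 each), and fry gave 0.811 for each. The flavonoid call was also lost without cfh1 replicate 3 (0.0785), and the cell division call without Col-0 replicate 2 (0.422), cfh1 replicate 1 (0.448) or the decoy libraries (0.0561), in a fit of the 2 groups alone (0.0638) and with no filter (0.0531). The heat shock list had a median log2 fold change of 0.06 and a mean of -0.23.

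The decoy line asks what a decoy form of CFH1 changes, and its seedlings differed from Col-0 at many genes, among them genes of photosynthesis and pigment. An effect of the decoy could not be told apart from a background other than Col-0 in any of these values, as described under other observations. Light harvesting and Rubisco genes rose, 15 of 21 measured and 20 when adjusted over the list alone, among them LHCB2.2 (1742 ± 204 against 572.9 ± 63.2 CPM, log2 fold change 1.61), LHCA3 (1.1) and LHCB4.1 (1.03). Chlorophyll synthesis genes rose, 9 of 16 by either adjustment, with the protochlorophyllide reductases PORB (1.25) and PORA (2.57) and the chlorophyll synthase gene CHLG (0.75). Flavonoid and anthocyanin genes fell, 12 of 19 and 13 when adjusted over the list alone, with LDOX at -3.72, TT19, of anthocyanin transport, at -3.00 and the MYB activator PAP1 at -4.96. None of these 3 lists had a member in the other direction by edgeR, by DESeq2 or at an unadjusted p under 0.05. Camera gave adjusted p 1.87e-06, 0.00285 and 0.000396 for these lists, but adjusted p = 0.674 for each with an estimated correlation, and fry gave 0.0103, 0.0142 and 0.0130. Without Col-0 replicate 2, 9 light harvesting genes were higher, and 9 without decoy replicate 1.

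CCA1 fell to 76.6 ± 24.8 CPM in the decoy from 154.3 ± 11.9 (log2 fold change -1.01, SE 0.209, adjusted p 0.00248), and LHY to 164.2 ± 34 from 277.1 ± 14.3 (-0.75, SE 0.179, adjusted p 0.00544). Of the dawn-phased clock genes, 5 of 11 fell, by either adjustment: CCA1, LHY, RVE1 (-0.79), RVE2 (-0.93) and RVE8. Of 10 evening-phased clock genes, GI (0.97), CHE (0.66) and FKF1 rose and ELF4 (-0.97), ELF3 and PRR3 fell, by either adjustment. At 1 collection time, these clock values cannot tell a changed level from a shifted cycle. Phytochrome and light signalling genes fell at 12 of 23 and rose at 2 (13 and 4 when adjusted over the list alone), with the bZIP factor HYH at -1.74, PCH1, which binds phytochrome B, at -1.28 and PIF4 at 1.13. PIL1 stood at 0.05 (SE 0.281) and did not pass. The camera test returned adjusted p 0.104 for the dawn-phased list, 0.686 for the evening-phased list and 0.124 for light signalling. With an estimated correlation these were adjusted p = 0.674, 0.998 and 0.674, and fry gave 0.0103, 0.717 and 0.0103. Without Col-0 replicate 1, 2 or 3 or decoy replicate 1, 6, 7, 6 and 6 light signalling genes were lower. Only 1 evening-phased gene was lower without Col-0 replicate 1, 2 or 3 or decoy replicate 1 or 3, and 1 dawn-phased gene was higher without decoy replicate 1.

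Auxin early response genes rose at 16 of 30 and fell at 3 in the decoy (also 16 and 3 when adjusted over the list alone), with the auxin-conjugating enzyme gene GH3.3 at 2.33 and SAUR23 at 1.92. SAUR19 had 0 counts in the decoy and 93 in Col-0, at least 24.8-fold lower. Shade and PIF-induced genes rose at 8 of 16, with PRE1 at 2.06, IAA29 at 2.74 and ST2A at 1.5, and XTH15 fell (the same counts when adjusted over the list alone). Cell wall loosening genes rose at 9 of 19, with the expansins EXPA8 (1.99) and EXPA11 (1.31) and XTH33 (1.39), and XTH15 and EXPB1 fell (9 and 3 when adjusted over the list alone). By camera the adjusted p was 0.00386 for the auxin list, 0.0117 for the shade list and 0.0743 for the cell wall list. With an estimated correlation these were adjusted p = 0.685, 0.674 and 0.685. Fry gave 0.0471, 0.0103 and 0.0181. Without Col-0 replicate 1 or 2 or decoy replicate 2, 1 cell wall gene was lower.

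Largest changes are given here and below for nuclear genes with a symbol, a mean log2 CPM of at least 1 and all 3 libraries of a genotype on 1 side of the other. Among the largest rises in the decoy within these limits, ESP, for the epithiospecifier protein that steers glucosinolate breakdown, stood at 4096 ± 1312 CPM against 12.0 ± 0.743 (log2 fold change 8.42, SE 0.329, adjusted p 3.15e-09). HISN6B, of histidine synthesis, had 800 counts in the decoy and 0 in Col-0, at least 333-fold higher. ADR1-L3, a member of a disease resistance family, had 1179 counts and 1, a ratio of 1473 (95% interval 263.9 to 58240). PDF1.2c (5.49), PCR1 (5.37), PR2 (4.16), HO3 (4.03) and AIG1 (4.03) completed the 8 largest rises within these limits, with AIG1 at 18.3 ± 22.1 and PDF1.2c at 13.7 ± 13.6 CPM. Among the largest falls within them, the phloem protein genes PP2-A8 (4129 counts in Col-0), PP2-A3 and PP2-A6 and the translation initiation gene eIF4E3 had 0 counts in all 3 decoy libraries. They were at least 1100-fold, 214.5-fold, 173-fold and 65.9-fold lower. AT14A had 3 counts against 3151, a ratio of 0.00119 (95% interval 0.000245 to 0.00348). HSD2, a hydroxysteroid dehydrogenase gene, stood at -10.33 and EXT12, an extensin gene, at -8.41. Of the genes lower in the decoy, 211 had 3 counts or fewer over its 3 libraries, whereas 4 of the genes lower with PIF3 over-expression and 0 of those lower in cfh1 had so few over theirs.

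In total, 4163 genes were higher and 4504 lower in the decoy than in Col-0, and 820 and 2174 with an absolute log2 fold change of at least 1. The split depends on the scaling: with library totals alone, 1720 were higher and 6929 lower, and the median of all tested genes was shifted by -0.25. Under that scaling 9 light harvesting genes were higher, 7 chlorophyll genes were higher and 1 lower, 15 flavonoid and 6 dawn-phased clock genes were lower, and cell wall loosening genes stood at 6 higher and 6 lower. Gibberellin and brassinosteroid genes stood at 5 and 5, and by edgeR under that same scaling 0 genes of the heat shock, jasmonate, B-box and flowering time lists were higher and 3, 3, 4 and 4 were lower.

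The remaining lists had members on both sides in the decoy or few members past the test. Of all 21235 tested genes, 4163 were higher and 4504 lower, so a few changed members do not set a list apart. Gibberellin and brassinosteroid genes were higher at 6 of 20 and lower at 4 (the same adjusted over the list alone), with the synthesis gene GA20OX1 at 2.0, GASA6 at 1.04 and GA2OX2 at 1.2. Salicylic acid and defence genes were higher at 5 of 20 (PR2, ALD1 at 2.29, PR1 at 4.64, PR5 and NPR1) and lower at 2 (EDS5 and EDS1), or 4 and 2 adjusted over the list alone. With library totals alone that list had 3 higher and 5 lower. Cold, drought and abscisic acid genes were higher at 3 of 21 (CBF2 at 1.66, GOLS1 at 0.64 and GOLS2) and lower at 4 (COR6.6 at -0.77, CBF3, LTI30 and ERD10), by either adjustment. Of 10 heat shock genes, MBF1C (0.56) and HSP18.2 were higher and HSP90.1 (-1.27), DREB2A (-1.42) and HSP101 lower, by either adjustment. Of 10 flowering time genes, SVP (0.48) was higher and CDF2 (-0.86), CDF1 (-0.57) and CDF3 lower, by either adjustment. Of 19 jasmonate genes, LOX4 (0.92), PDF1.2 and AOC1 were higher and VSP1 (-1.13) and JAZ1 (-0.46) lower, and adjusted over the list alone 0 were higher and 1 lower (4 and 3 at an unadjusted p under 0.05, 3 and 2 by DESeq2). Of 15 root markers, PYK10 (0.85) and NRT2.1 were higher and NAI2 (-0.75) and EXPA7 (-1.38) lower, by either adjustment. Of 13 B-box factors, BBX24 (0.39) and BBX28 were higher and COL2 (-0.72) and BBX32 (-0.81) lower, by either adjustment. Of 10 cell division genes, KNOLLE (-0.91) and CYCB1;1 (-0.70) were lower, or 1 adjusted over the list alone. Camera adjusted p in these 9 lists ran from 0.416 to 0.997. Fry gave 0.0471 for flowering time genes, lower on balance (camera adjusted p = 0.7645 with an estimated correlation), and 0.368 to 0.773 for the rest. With library totals alone, MBF1C (0.32), SVP (0.22), BBX24 (0.13), GOLS1 (0.38), LOX4 (0.66) and, of the evening-phased list, CHE (0.39) did not pass.

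Single libraries decided several of these smaller counts in the decoy. Without Col-0 replicate 1 or 2, 3 salicylic acid and defence genes were higher; without Col-0 replicate 1, 2 or 3, 1 was lower, and without decoy replicate 3, 10 were lower. Cold, drought and abscisic acid genes stood at 1 higher without Col-0 replicate 1 or decoy replicate 3 and 5 higher without Col-0 replicate 3, and at 1 lower without Col-0 replicate 3 and 2 lower without decoy replicate 1. In that list GOLS1 did not pass without Col-0 replicate 1 (0.56) or decoy replicate 3 (0.52). Heat shock genes stood at 1 higher without decoy replicate 3, and flowering time genes at 2 higher without decoy replicate 1. Jasmonate genes stood at 0 or 1 higher without Col-0 replicate 1 (1), 2 (0) or 3 (1) or decoy replicate 1 (1) or 3 (0), and at 1 lower without Col-0 replicate 1, 2 or 3 or decoy replicate 1 or 2. LOX4 did not pass without Col-0 replicate 2 (0.83) or 3 (0.89) or decoy replicate 1 (0.93) or 3 (0.61), and JAZ1 without Col-0 replicate 1 (-0.45), 2 (-0.44) or 3 (-0.49) or decoy replicate 1 (-0.50) or 2 (-0.31). Of the root markers, 1 was higher without Col-0 replicate 1 or 2 or decoy replicate 3. B-box factors stood at 0 higher without Col-0 replicate 1 or 2 and 1 without decoy replicate 1 or 3, and at 1 lower without Col-0 replicate 1 or 2 or decoy replicate 1 or 2. BBX24 did not pass without Col-0 replicate 1 (0.37) or 2 (0.37), and BBX32 without Col-0 replicate 1 (-0.83) or 2 (-0.70) or decoy replicate 1 (-0.78) or 2 (-0.80). The cell division gene CYCB1;1 did not pass without Col-0 replicate 1 (-0.75), 2 (-0.63) or 3 (-0.72) or decoy replicate 1 (-0.51) or 3 (-0.73), which left 1 gene of that list, nor in a fit of the 2 groups alone (-0.72).

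Over-expression of PIF3 asks what more of this phytochrome-interacting factor changes in red light, and drought-responsive and shade-responsive genes rose while genes of photosynthesis fell. Cold, drought and abscisic acid genes rose at 16 of 21 (18 when adjusted over the list alone), with P5CS1, of proline synthesis, at 737.4 ± 294.8 against 75.7 ± 44.7 CPM (log2 fold change 3.29, SE 0.403, adjusted p 8.74e-04) and the phosphatase genes ABI1 at 1.03 and ABI2 at 1.63. Shade and PIF-induced genes rose at 9 of 16 (11 when adjusted over the list alone), with HFR1 at 31.9 ± 8.17 against 3.46 ± 0.639 CPM (3.21), ST2A at 3.03 and IAA29 at 2.91. Light harvesting and Rubisco genes fell at 12 of 21 (19 when adjusted over the list alone), with LHCB1.1 at 1434 ± 371 against 2963 ± 135 CPM (-1.05), LHCB2.3 at -1.11 and LHCA1 at -0.83. Chlorophyll synthesis genes fell at 7 of 16 (13 when adjusted over the list alone), with HEMA1, for the first committed step, at -1.31, the magnesium chelatase gene GUN5 at -0.89 and CHLM at -0.62. None of these 4 lists had a member in the other direction by edgeR, by DESeq2 or at an unadjusted p under 0.05. PIL1 stood at 0.93 (SE 0.268, adjusted p 0.0369).

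Camera gave adjusted p 2.33e-14 for the cold, drought and abscisic acid list, 1.86e-06 for the shade list, 2.56e-11 for light harvesting and Rubisco and 1.86e-06 for chlorophyll synthesis with PIF3 over-expression. With an estimated correlation these were adjusted p = 0.225, 0.225, 0.304 and 0.304, and fry gave 0.0019, 0.0019, 0.0117 and 0.0117. Without Col-0 replicate 1 or 2, 9 and 10 cold, drought and abscisic acid genes were higher. Shade genes stood at 3, 4 and 3 higher without Col-0 replicate 1, 2 and 3 and at 5 without PIF3 over-expression replicate 2. Light harvesting genes stood at 3, 4 and 7 lower without Col-0 replicate 1, 2 and 3 and at 4 without PIF3 over-expression replicate 1 or 3. Chlorophyll genes stood at 1, 1 and 3 lower without Col-0 replicate 1, 2 and 3 and at 2 without PIF3 over-expression replicate 1 or 3. PIL1 did not pass without Col-0 replicate 1 (0.90), 2 (0.91) or 3 (0.98) or PIF3 over-expression replicate 2 (0.93) or 3 (0.72), nor with replicate number as a block (0.92). GUN5 did not pass without Col-0 replicate 1 (-0.91), 2 (-0.90) or 3 (-0.85) or PIF3 over-expression replicate 1 (-0.76) or 3 (-0.85), and CHLM without Col-0 replicate 1 (-0.59) or 2 (-0.64).

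**Figure D4:**
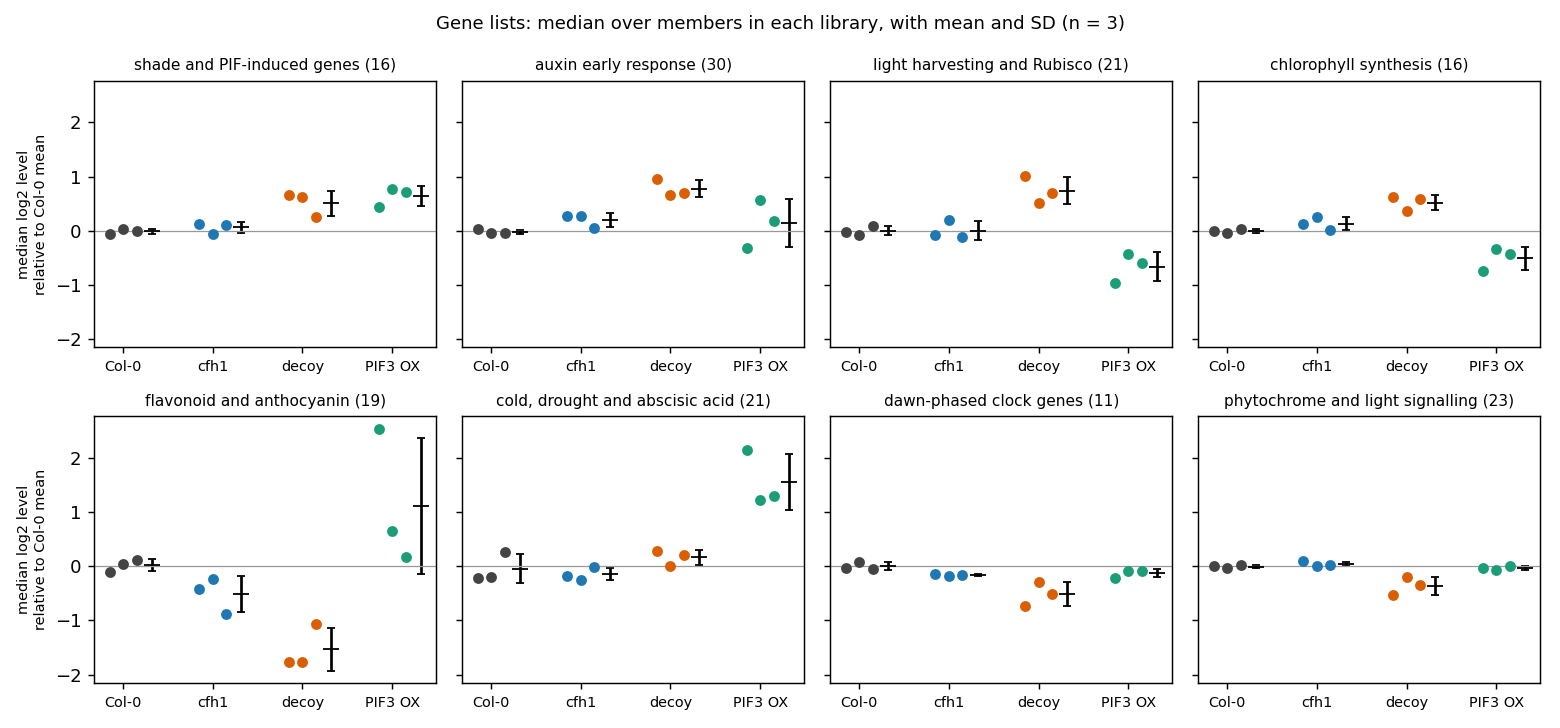
Median log2 CPM over the members of 8 gene lists in each library, relative to the Col-0 mean (points), with the mean and SD of each genotype (n = 3). The cold, drought and abscisic acid list stands at 2.14, 1.22 and 1.29 in PIF3 over-expression replicates 1, 2 and 3 and the flavonoid and anthocyanin list at 2.54, 0.645 and 0.163.

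Flavonoid and anthocyanin genes rose at 9 of 19 with PIF3 over-expression (10 when adjusted over the list alone), with TT19 at 2.42, PAP1 at 2.53 and the glucosyltransferase gene UGT75C1 at 2.43, and none fell. Heat shock genes rose at 5 of 10 by either adjustment, namely HSP70 (2.24), HSP22 (5.34), MBF1C (0.78), DREB2A and HSP17.6A. Gibberellin and brassinosteroid genes rose at 4 of 20, namely GASA4 (1.14), the receptor gene GID1A (0.54), GA20OX2 (1.16) and GID1C, and adjusted over the list alone 5 were higher and 1 lower. For these lists camera gave adjusted p 6.31e-04, 0.0190 and 0.0445, with adjusted p = 0.672, 0.236 and 0.304 with an estimated correlation, and fry gave 0.170, 0.00642 and 0.0152. The camera call of the gibberellin and brassinosteroid list was also lost without Col-0 replicate 3 (0.0731) or PIF3 over-expression replicate 2 (0.0769) or 3 (0.0870), with library totals alone (0.0680), in a fit of the 2 groups alone (0.0552), with replicate number as a block (0.0506) and without the decoy libraries (0.0569), and that of the heat shock list without genes silent in a group (0.0791). Flavonoid genes stood at 2, 4 and 4 higher without Col-0 replicate 1, Col-0 replicate 2 and PIF3 over-expression replicate 1, and UGT75C1 did not pass without Col-0 replicate 1 (2.18). Heat shock genes stood at 3 higher without any 1 of those 3 libraries. Gibberellin and brassinosteroid genes stood at 2 higher without Col-0 replicate 1 or PIF3 over-expression replicate 1, and GA20OX2 did not pass without either (1.13 and 1.1).

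Within the same limits of symbol, expression and library order, the 8 largest rises with PIF3 over-expression were these. HSFA6A, a heat shock factor, stood at 36.7 ± 13.6 against 1.42 ± 2.16 CPM (log2 fold change 4.75, SE 0.808, adjusted p 0.00403), HAI3 at 4.65, TSPO at 4.61, HAI2 at 4.38, LEA7 at 4.31 and LEA4-5 at 4.22. RD29B averaged 346.2 ± 312.3 against 14.8 ± 18.7 CPM (4.56) and RAB18, a dehydrin gene, 1462 ± 1587 against 70.6 ± 104.2 (4.38). The 8 largest falls within these limits were in MRD1 (1.88 ± 0.397 against 43.5 ± 3.05 CPM, -4.53), the cytochrome P450 gene CYP712A1 (-4.08), MEE3 (-3.23), NEET (-3.15), GASA5 (-3.14), HEI10 (-2.37), CIPK20 (-2.25) and HMA3 (-2.08). CCA1 (-0.31, SE 0.206) and LHY (-0.48, SE 0.178, adjusted p 0.0959) did not pass, though LHY did by DESeq2 (-0.49), in a fit of the 2 groups alone (-0.48) and without the decoy libraries (-0.47). RAB18 did not pass without Col-0 replicate 1 (3.85), Col-0 replicate 2 (3.87) or PIF3 over-expression replicate 1 (2.95), TSPO without Col-0 replicate 1 (4.11) or PIF3 over-expression replicate 1 (3.05), and LEA7 without Col-0 replicate 1 (3.85).

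In total, 1275 genes were higher and 1554 lower with PIF3 over-expression than in Col-0. With library totals alone, the share higher went from 45.07% to 61.46%, so the side that holds most calls depends on the scaling. Without Col-0 replicate 1, 413 were higher and 461 lower, without Col-0 replicate 2, 530 and 659, and without PIF3 over-expression replicate 1, 543 and 539. Without PIF3 over-expression replicate 3, 969 were lower.

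Auxin early response genes rose at 8 of 30 with PIF3 over-expression and SAUR62 fell (8 and 2 adjusted over the list alone), with IAA29, GH3.5 (0.96) and GH3.6 (0.65) among the 8. Of the flowering time genes, FLC (1.37), the floral integrator SOC1 (0.84) and the florigen gene FT rose, by either adjustment, with FT at 74 counts against 5. Jasmonate genes rose at 4 of 19 (MYC2 at 0.53, VSP2 at 1.43, JAZ3 and OPR3), and JAZ9 (-0.87) and JAZ6 fell, or 6 and 3 adjusted over the list alone. Of light signalling genes, PIF6 (1.79) and PIF4 rose and HYH (-1.06), PIF7 (-0.60) and HY5 fell, or 4 and 4 adjusted over the list alone. Of the cell wall genes, EXPA11 (1.21), XTH19 (1.06) and XTH33 (0.76) rose and XTH9 fell, and of the root markers, BGLU22 (0.82) and BGLU21 (0.75) rose and IRT1 (-1.44) fell, both by either adjustment. ALD1 (-1.86) and PR5 (-1.01) were lower in the salicylic acid and defence list, or 1 gene adjusted over the list alone. The dawn-phased clock list had 1 lower gene, LNK2, and the evening-phased list 1 higher, FKF1, by either adjustment, and the B-box list had 1 lower, COL2, also by DESeq2, and 0 adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05). In the cell division list 0 of 10 passed by edgeR with either adjustment, 0 at an unadjusted p under 0.05 and 0 by DESeq2. Camera adjusted p in these 11 lists ran from 0.126 to 0.864. The median, mean and test differed in sign for jasmonate and light signalling here, and in the decoy for B-box, cold and drought, heat shock and gibberellin genes.

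Several of these smaller counts with PIF3 over-expression rested on single libraries. Auxin genes stood at 2, 3 and 4 higher without Col-0 replicate 1, 2 and 3 and at 4 and 5 without PIF3 over-expression replicate 2 and 3, and GH3.6 did not pass without Col-0 replicate 1 (0.62) or 2 (0.61). The flowering gene FT did not pass without Col-0 replicate 1 (3.38) or 2 (3.39) or PIF3 over-expression replicate 1 (3.35). Jasmonate genes stood at 2 higher without PIF3 over-expression replicate 1, and at 0 lower without Col-0 replicate 1 and 1 lower without Col-0 replicate 2 or PIF3 over-expression replicate 1. In that list JAZ9 did not pass without Col-0 replicate 1 (-0.80). Light signalling genes stood at 1 higher without Col-0 replicate 1 or 2 or PIF3 over-expression replicate 3 and at 1 lower without Col-0 replicate 1 or PIF3 over-expression replicate 1, each of which also left PIF7 short of the test (-0.59 and -0.49). XTH33 did not pass without Col-0 replicate 1 (0.76) or 2 (0.69) or PIF3 over-expression replicate 1 (0.60). BGLU21 did not pass without Col-0 replicate 1 (0.68), 2 (0.83) or 3 (0.75) or PIF3 over-expression replicate 1 (0.45), and IRT1 without any single library of the comparison (-1.54 to -1.30). The counts of 1 lower cell wall gene and 1 lower B-box gene went to 0 without Col-0 replicate 1 or 2 or PIF3 over-expression replicate 1 or 3, and the B-box count also without Col-0 replicate 3 and, like the cell wall count, with library totals alone. In the dawn-phased list 0 genes were lower without Col-0 replicate 2 or PIF3 over-expression replicate 1. In the evening-phased list 0 genes were higher without Col-0 replicate 1 or 2 or PIF3 over-expression replicate 1 or 3, and 2 were higher and 1 lower without PIF3 over-expression replicate 2. ALD1 did not pass without Col-0 replicate 1 (-1.68) or PIF3 over-expression replicate 1 (-1.72) or 3 (-1.72), and PR5 without Col-0 replicate 1 (-1.04), 2 (-1.19) or 3 (-0.77) or PIF3 over-expression replicate 1 (-0.77) or 3 (-1.01). PR5 also did not pass with library totals alone (-0.93), in a fit of the 2 groups alone (-1.01) or with replicate number as a block (-1.03), nor did BGLU21 (0.75) and IRT1 (-1.43) with the block, nor PIF7 with library totals alone (-0.52).

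The mutant and the decoy both alter CFH1 per the labels, but a difference in background stays open for the decoy. They differed from each other at light harvesting and Rubisco genes and at single genes of chlorophyll synthesis, anthocyanin and other lists. Light harvesting and Rubisco genes were lower in cfh1 than in the decoy at 14 of 21 (19 adjusted over the list alone), with LHCB2.2 at -1.68, and chlorophyll synthesis genes at 8 of 16 by either adjustment. Flavonoid and anthocyanin genes were higher at 9 of 19 (10 adjusted over the list alone), with PAP1 at 3.91. CCA1 was higher at 0.72 (SE 0.208, adjusted p 0.0185) and LHY at 0.57 (SE 0.178, adjusted p 0.0268), with RVE1, RVE2 and RVE8 making 5 of 11 dawn-phased genes by either adjustment. Within the limits above, the largest differences included PP2-A8, PP2-A3, PP2-A6 and HSD2 (higher in cfh1) and ADR1-L3, UBP6 (-9.17), MRD1 (-8.87), ESP (-8.23) and HISN6B (-7.35). Camera gave adjusted p 1.17e-07 for light harvesting, 0.0143 for chlorophyll and 0.0143 for flavonoid genes, with adjusted p = 0.887 each with an estimated correlation, and 0.0585 for flavonoid genes without cfh1 replicate 2. Fry gave 0.0123 for light harvesting and did not pass for the other 2 (0.0659 each). Auxin early response genes were higher at 5 of 30 and lower at 15, and shade and PIF-induced genes higher at 1 of 16 and lower at 7. Light signalling genes were higher at 11 of 23 and lower at 2. For these lists in order camera gave adjusted p 0.04005, 0.0299 and 0.0508, with adjusted p = 0.960, 0.887 and 0.887 with an estimated correlation, and fry gave 0.249, 0.0407 and 0.00579. In total, 3864 genes were higher and 3191 lower, but 6039 and 1304 with library totals alone, under which the median of all tested genes was shifted by 0.23 and chlorophyll genes stood at 3 lower and 1 higher. Without cfh1 replicate 1, 2005 were lower. Chlorophyll genes stood at 3 lower without cfh1 replicate 1 or 3 or decoy replicate 1, and at 4 without decoy replicate 3, and flavonoid genes at 5 higher without decoy replicate 1 or 3. Dawn-phased genes stood at 2 higher without cfh1 replicate 1 or 2, 3 higher and 1 lower without decoy replicate 1, and 1 lower without cfh1 replicate 3. CCA1 did not pass without cfh1 replicate 1 (0.67) or 2 (0.63), nor LHY without cfh1 replicate 1 (0.49) or 2 (0.51) or decoy replicate 1 (0.41), and neither passed in a fit of the 2 groups alone (0.72 and 0.57). PIF3 (-0.39), PHYB (-0.09), TOC1 (0.07) and PIL1 (-0.25) did not pass, though PIF3 did without cfh1 replicate 3 (-0.61).

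Against PIF3 over-expression, cfh1 had lower drought, anthocyanin and shade genes and higher genes of photosynthesis. Cold, drought and abscisic acid genes were lower at 14 of 21 (19 adjusted over the list alone), with P5CS1 at -3.40, flavonoid and anthocyanin genes at 10 of 19 (13 adjusted over the list alone), and shade and PIF-induced genes at 9 of 16, with HFR1 at -2.60. Adjusted over the list alone, 9 shade genes were lower and 1 higher. Light harvesting and Rubisco genes were higher at 11 of 21 (16 adjusted over the list alone) and chlorophyll synthesis genes at 11 of 16 (14), with HEMA1 at 1.34. PIF3 stood at -3.74 and PIL1 at -1.13 (adjusted p 0.0186), and PHYB (-0.05), CCA1 (0.02), LHY (0.30) and TOC1 (0.09) did not pass. Within the limits above, the largest differences were in PDF1.2 (5.50), CYP712A1 (3.56), MEE3 (3.05), NEET (2.81) and GASA5 (2.22), and in UBP6 (-9.00), LTP4 (-7.08), TSPO (-6.31), RAB18 (-6.22) and LEA7 (-6.00). Camera gave adjusted p 3.60e-15, 2.31e-07, 2.93e-05, 2.71e-10 and 1.00e-08 for these lists in order, with adjusted p = 0.215, 0.352, 0.215, 0.351 and 0.215 with an estimated correlation, and fry gave 0.00248, 0.0294, 0.004025, 0.0161 and 0.004025. In total, 1524 genes were higher and 1211 lower. With library totals alone, 904 were higher and 1664 lower, with a median shift of -0.10, so the side that holds most calls depends on the scaling.

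Several libraries decided the values of cfh1 against PIF3 over-expression. Without cfh1 replicate 1, cfh1 replicate 2 and PIF3 over-expression replicate 1, 544, 367 and 391 genes were higher and 597, 532 and 535 lower, and without PIF3 over-expression replicate 3, 824 were higher. Light harvesting genes stood at 3, 0, 2 and 3 higher without these 4 libraries in order, and chlorophyll genes at 3, 3, 3 and 6. Shade genes stood at 4, 2 and 5 lower without cfh1 replicate 1, cfh1 replicate 2 and PIF3 over-expression replicate 3. PIL1 did not pass without those same 3 libraries (-1.10, -1.16 and -0.92). PDF1.2 did not pass without cfh1 replicate 1 (3.0) or PIF3 over-expression replicate 1 (5.15), 2 (5.36) or 3 (6.20), or with replicate number as a block (5.16), NEET without cfh1 replicate 2 (2.62) or PIF3 over-expression replicate 1 (2.35), and LTP4 without cfh1 replicate 2 (-6.78).

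All 21 light harvesting and Rubisco genes were higher in the decoy than with PIF3 over-expression, by either adjustment, with LHCB2.2 at 2.08 (SE 0.190) and LHCB1.1 at 1.58. Chlorophyll synthesis genes were higher at 14 of 16 by either adjustment, with HEMA1 at 1.82. Flavonoid and anthocyanin genes were lower at 15 of 19 by either adjustment, with LDOX at -5.70, and cold, drought and abscisic acid genes at 15 of 21 (16 adjusted over the list alone), with RD29B at -6.25. CCA1 was lower at -0.70 (SE 0.208, adjusted p 0.0158), as were RVE1, RVE2, RVE8 and LNK1, 5 of 11 dawn-phased genes by either adjustment, and PIF3 (-3.35) and PIL1 (-0.88) were lower. Within the limits above, the largest differences included HISN6B, ADR1-L3, PDF1.2c (8.36), ESP (8.27) and PDF1.2 (5.94), and PP2-A8, AT14A, HSD2 (-10.23) and eIF4E3. For the first 4 lists camera gave adjusted p 1.73e-12, 2.11e-07, 4.99e-06 and 3.72e-05, with adjusted p = 0.535 each with an estimated correlation, and fry gave 3.67e-04, 3.67e-04, 0.00109 and 0.001265. In total, 4363 genes were higher and 4827 lower, but 1973 and 9120 with library totals alone, under which the median of all tested genes was shifted by -0.36. Dawn-phased genes stood at 3 lower and 2 higher without decoy replicate 1 and at 2 lower and 1 higher without PIF3 over-expression replicate 2. CCA1 did not pass without PIF3 over-expression replicate 2 (-0.63), nor PIL1 without decoy replicate 3 (-0.82) or PIF3 over-expression replicate 3 (-0.67), and neither passed in a fit of the 2 groups alone (-0.70 and -0.87). PHYB (0.04), LHY (-0.27) and TOC1 (0.02) did not pass, though with library totals alone PHYB (-0.31) and LHY (-0.59) did.

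Genes changed in the same direction in 2 lines were few for cfh1. With the decoy it shared AT5G37940 (higher) and HEI10 and OBE1 (lower), 3 genes against 3.13 for independent lists, while MRD1, AT2G32560, AT1G75945 and AT4G14270 were called in opposite directions. With PIF3 over-expression it shared AT5G37940, MRD1 and HEI10, 3 genes against 1.06, and AT4G14270 was called in opposite directions. AT5G37940 (3.15 in cfh1, 4.40 in the decoy and 3.83 with PIF3 over-expression) and HEI10 (-2.98, -1.19 and -2.37) thus passed the same way in all 3 lines. Values of the common Col-0 libraries may account for the calls of AT5G37940 and HEI10. For MRD1, such an account is argued against by the decoy libraries, at 79.67 to 118.4 CPM against 40.01 to 45.34 in Col-0. MRD1 stood at 0.183 to 0.2618 CPM in cfh1 and 1.521 to 2.305 with PIF3 over-expression, low against the decoy too. The decoy and PIF3 over-expression shared 802 genes, 306 higher and 496 lower, against 579.6 for independent lists, while 562 were called in opposite directions. Their shared rises included AT2G07000 (6.06 in the decoy and 4.24 with PIF3 over-expression), AT5G37940 (4.40 and 3.83), CYP96A15 (6.57 and 3.53), AT5G24240 (3.38 and 4.83) and the auxin repressor gene IAA29 (2.74 and 2.91). Their shared falls included AT1G59920, AT3G02242 (-2.89 and -3.44), AT1G29000 (-4.13 and -2.55), AT2G15042 and the plastid gene ATCG00800 (-3.81 and -2.41). Both comparisons use the same Col-0 libraries. Simulated lines with no change shared 0 genes over 20 draws, but each had at most 2 calls to share, so this 0 sets no level for the overlaps. A count at an unadjusted p under 0.05 was therefore added after the results were seen. There the simulated lines shared 223.2, 225.4 and 220.5 genes on average through the common controls alone, and the data 557 for cfh1 and the decoy, 308 for cfh1 and PIF3 over-expression and 1985 for the decoy and PIF3 over-expression, against 241.7, 131.2 and 1442 for independent lists. These counts moved with single libraries: cfh1 and the decoy shared 320, 258 and 308 without Col-0 replicate 1, Col-0 replicate 2 and cfh1 replicate 1, and 935 and 863 without decoy replicate 1 and 2. For cfh1 and PIF3 over-expression they were 160 without Col-0 replicate 1 or 2, 184 without cfh1 replicate 1 and 551 without Col-0 replicate 3, and for the decoy and PIF3 over-expression 1273 without Col-0 replicate 1. Log2 fold changes correlated at 0.228, 0.204 and 0.0844 for these pairs, below the simulated 0.490, 0.503 and 0.496, with covariances of 0.0942, 0.0397 and 0.0630 against the simulated 0.0350, 0.0354 and 0.0351. For cfh1 and PIF3 over-expression the covariance went to 0.01435 without cfh1 replicate 3 (correlation 0.0571), 0.01948 with a stricter filter and 0.03395 without genes silent in a group. The simulated values were made for the main fit alone, so they set no level for other settings. On which side of such a level these covariances lie was not tested. Without Col-0 replicate 3 the covariances were 0.149, 0.104 and 0.143 and the correlations 0.284, 0.382 and 0.158. With 3 Col-0 libraries the controls were not divided between the comparisons, so part of the shared genes may come from the common controls. Without Col-0 replicate 1, Col-0 replicate 2 and PIF3 over-expression replicate 1, the decoy and PIF3 over-expression shared 230, 298 and 352 genes.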

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

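The fits without the decoy libraries and without genes at 3 counts or fewer in a whole group were chosen only after the results were seen. Of 230 fold changes of named genes, leaving out 1 library kept the call and direction in 1270 comparisons, ended the call in 109 and made 1 past the test, and the other settings kept 2105, ended 23, made 4 and reversed 1. The reversed value is PHYB in the decoy against PIF3 over-expression, 0.04 as reported and -0.31 and past the test with library totals alone. Of the 15 counts of genes, 80 values without 1 library stayed within 1.5 times and 19 did not, and 124 and 33 in the other settings. Of 216 counts of list members, 1010 and 286 did so without 1 library and 1993 and 275 in the other settings. Of 15 camera calls against Col-0, 84 values were kept and 6 lost without 1 library, and 133 kept and 27 lost in the other settings. Camera calls between lines are not in this tally. Of those printed, auxin and shade genes in cfh1 against the decoy set aside, leaving out 1 library ended 1. That was the call of flavonoid genes in cfh1 against the decoy without cfh1 replicate 2 (0.0585). The causes were not tested, apart from fewer libraries or genes where the setting itself removes them. The self-test puts the limit: 14% of 1.5-fold changes were recovered, in genes at a level of 1 CPM or more.

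With library totals alone, cfh1 had 6 higher genes than Col-0, the decoy 1720 higher and 6929 lower, cfh1 against the decoy 6039 and 1304, cfh1 against PIF3 over-expression 904 higher, the decoy against PIF3 over-expression 1973 and 9120, and cfh1 shared 7 genes with the decoy. By DESeq2, cfh1 had 7 higher and 31 lower genes than Col-0 and shared 17 with the decoy and 11 with PIF3 over-expression. In fits of the 2 groups alone, PIF3 over-expression had 1930 higher and 2349 lower genes than Col-0, and cfh1 against the decoy 2522 and 1903. With an absolute log2 fold change of at least 1, the decoy had 820 higher and 2174 lower genes than Col-0, PIF3 over-expression 523 and 444, cfh1 against the decoy 1832 and 722, cfh1 against PIF3 over-expression 331 and 566 and the decoy against PIF3 over-expression 1298 and 2270, with 232 genes shared by the decoy and PIF3 over-expression. Without the decoy libraries, cfh1 had 5 higher genes, PIF3 over-expression 2020 higher, cfh1 against PIF3 over-expression 1860 lower, and cfh1 shared 5 with PIF3 over-expression. Without genes silent in a group, cfh1 had 1 higher gene.

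Leaving out single libraries gave 7 to 12 lower genes in cfh1, 413 to 1090 higher and 461 to 1429 lower with PIF3 over-expression, 2005 to 3736 lower in cfh1 than in the decoy, 367 to 1518 higher and 532 to 1088 lower in cfh1 than with PIF3 over-expression, and 230 to 1003 shared by the decoy and PIF3 over-expression. The lowest came without cfh1 replicate 2 (7, 367 and 532), Col-0 replicate 1 (413, 461 and 230) and cfh1 replicate 1 (2005). Also over 1.5 times lower were the counts with PIF3 over-expression without Col-0 replicate 2 (530 and 659, with 298 shared), PIF3 over-expression replicate 1 (543 and 539, with 352 shared) and replicate 3 (969 lower). For cfh1 against PIF3 over-expression they were those without cfh1 replicate 1 (544 and 597) and PIF3 over-expression replicate 1 (391 and 535) and replicate 3 (824 higher).

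Replicate numbers recur across genotypes, so each comparison was also fitted with the number as a replicate block. It gave 2 higher and 11 lower genes for cfh1, 3703 and 4292 for the decoy and 1046 and 1326 for PIF3 over-expression against Col-0, 3628 and 2725 for cfh1 against the decoy, 1177 and 991 for cfh1 against PIF3 over-expression and 4024 and 4621 for the decoy against PIF3 over-expression. Shared genes were 2, 2 and 701. The block ended the calls of AT1G20270 (-1.06) and AT5G37940 (3.16) in cfh1, of PIL1 (0.92), BGLU21 (0.75), IRT1 (-1.43) and PR5 (-1.03) with PIF3 over-expression, and of PDF1.2 (5.16) in cfh1 against PIF3 over-expression. Fits of the 2 groups alone ended those of AT1G20270 and AT5G37940 in cfh1, CYCB1;1 (-0.72) in the decoy, PR5 with PIF3 over-expression, CCA1 (0.72) and LHY (0.57) in cfh1 against the decoy, and CCA1 (-0.70) and PIL1 (-0.87) in the decoy against PIF3 over-expression. Libraries of the same number correlated across genes at -0.364 to 0.271 (18 pairs, median -0.052, against 0.008 for different numbers) after removal of genotype means, and 2 of 12 libraries correlated best with their own number. No pairing by number was thus seen, but values from so few libraries cannot exclude a shared batch.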

Other observations

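The tests of gene classes, of genes at or near 0 in the decoy, of the cold, drought and abscisic acid list, of AT2G32560 and of other splits of the libraries were chosen only after the results were seen. Products in the annotation group genes into classes that the lists did not cover, and 60 Fisher's exact tests compared each class with all other tested genes. In the decoy, disease resistance genes, which encode receptors of pathogen effectors, were lower at 77 of 174 (44.3% against 21.0% of other genes, adjusted p 2.58e-10) and higher at 15 (8.62% against 19.7%, adjusted p 9.14e-04). Glutathione S-transferase genes, of detoxification, were lower at 27 of 53 (50.9% against 21.1%, adjusted p 3.32e-05). Ribosomal protein genes were lower less often than other genes, at 26 of 360 (7.22% against 21.5%, adjusted p 2.24e-11). Late embryogenesis abundant protein genes, which act in drying seeds and water-stressed tissue, were lower at 26 of 71 (36.6% against 21.2%, adjusted p 0.0158) and higher less often than others, at 3 (4.23% against 19.7%, adjusted p 0.00283), as were WRKY factors, at 3 of 61 (4.92% against 19.6%, adjusted p 0.01). With PIF3 over-expression, late embryogenesis abundant protein genes were higher at 16 of 71 (22.5% against 5.95%, adjusted p 5.40e-05), and cytochrome P450 genes at 25 of 187 (13.4% against 5.94%, adjusted p 0.00115). Receptor-like kinase genes were lower there at 19 of 100 (19.0% against 7.26%, adjusted p 9.14e-04). Ribosomal protein genes were lower at 40 of 360 (11.1% against 7.25%, adjusted p 0.0358) and higher less often than others, at 4 (1.11% against 6.09%, adjusted p 6.12e-05), and F-box genes were lower less often, at 3 of 186 (1.61% against 7.37%, adjusted p 0.00563). Genes of a class are not independent, so these p-values describe the classes in these libraries.

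Of the genes lower in the decoy, 211 had 3 counts or fewer over its 3 libraries, among them PP2-A8, PP2-A3 and PP2-A6, and 57 genes at that level in the decoy had at least 50 counts in each of the 9 other libraries, against 0 such genes for any other genotype. Low depth is argued against by the total counts of decoy replicates 2 and 3 (34345088 and 33122683, against 28581600 to 33583770 in Col-0), though replicate 1 had 21914394. The counts expected for the 211 genes at their Col-0 level (median 70, lowest 9.03) do not test depth, since these genes were picked as lower. An account by 1 deletion near an inserted transgene is argued against by their spread, with at most 27% on 1 chromosome. A strain variant against the reference, that is a decoy line in a background other than the Col-0 of the labels, may account for part of them. Disease resistance genes, which vary between accessions, made up 12 of the 211 (5.69%) against 160 of 20900 others (0.766%, odds ratio 7.81, 95% interval 3.89 to 14.3, one-sided Fisher's exact p 1.69e-07). But the 211 were picked as lower, and this class as a whole was lower more often (44.3% against 21.0% of other genes). That test therefore cannot tell a strain variant from other causes of the fall, and neighbouring genes of the class are not independent. ESP, at 4096 CPM in the decoy and 12.0 in Col-0, is known to be expressed in some accessions and little in Col-0. An effect of the decoy itself was not tested apart from the background, since both come with the same 3 libraries. All values of the decoy, against Col-0 or against another line, carry the same limit.

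The cold, drought and abscisic acid list was higher at 16 of 21 genes with PIF3 over-expression, with large spread between libraries in RAB18 and RD29B. That replicate 1 alone gave the pattern is argued against by 11 members still higher without that library. Low values in the Col-0 libraries are argued against by 14 members higher than in cfh1. A difference in water status or handling between plates could also raise these genes, and no label gives plate or batch, so it and an effect of PIF3 stay open, both untested. Replicate 1 also stood furthest from Col-0 in the light harvesting (-0.960, against -0.436 and -0.596 in replicates 2 and 3) and flavonoid lists (2.54, against 0.645 and 0.163), but not in the shade list (0.434, against 0.780 and 0.708). The values of these lists with PIF3 over-expression carry the same limit.

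AT2G32560, an F-box gene, fell to 16.6 ± 1.204 CPM in cfh1 and rose to 343.1 ± 45.1 in the decoy from 41.0 ± 5.83 in Col-0, at log2 fold changes of -1.31 and 3.06. It may be the locus labelled CFH1, since a decoy line over-produces part of its own gene, but it was picked for these 2 changes, so they do not test that. For description, 2.69% of the 186 tested F-box genes (5 genes) rose more in the decoy. The call in cfh1 was lost without cfh1 replicate 1 (-1.26) or 2 (-1.31), and genes that rise in the decoy through its background stay open as an alternative.

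Pairs of neighbouring genes on chromosome 1 were low together in cfh1. Whether the cfh1 mutation or another difference of the line lowered them was not tested. UBP6 had 3, 1 and 5 counts in its 3 libraries and AT1G51720 had 7, 4 and 12. MRD1 had 6, 7 and 6 counts in cfh1 and 64, 51 and 82 with PIF3 over-expression, and HEI10 had 41, 24 and 32 in cfh1, 66, 58 and 51 with PIF3 over-expression, 68, 136 and 95 in the decoy and 297, 295 and 257 in Col-0.

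Any 6 libraries of 2 genotypes have 10 splits into 3 and 3, too few for a share under 0.05. In 2-group fits only 1 split, the real one, called as many genes in each comparison, and the highest other split called 0. Each other split mixes the 2 genotypes, so a difference between them adds to the spread within its groups. These values of 0 therefore set no level for unchanged groups. The real splits called 16 genes for cfh1, 6693 for the decoy and 4279 for PIF3 over-expression against Col-0, and 4425 for cfh1 against the decoy, 2583 for cfh1 against PIF3 over-expression and 6580 for the decoy against PIF3 over-expression.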
